A study of Homo sapiens with 6 samples.

How the data were processed

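H4K5la was measured by ChIP-seq in PLC/PRF/5 hepatocellular carcinoma cells, without treatment and after culture with 20 mM lactate for 24 h. Groups and replicate numbers were taken from the sample labels, giving 2 control and 2 lactate libraries with a peak list. The 2 input libraries have no peak list and were not analysed here. Per the labels' protocols, chromatin was prepared and precipitated with commercial ChIP kits, and reads were trimmed, aligned and cleared of duplicates. Per the submitters' processing notes, the tools included FastQC 0.11.7, Trimmomatic 0.38, Bowtie2 2.3.4.2, SAMtools 1.9, Picard 2.18.11 and MACS2 2.2.6, and the genome build was hg38. The same notes name featureCounts 1.6.3 and RSEM, and give no role for either tool.

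Each deposited list holds the peaks of a single library, so replicates could be compared as separate lists. The authors' deposited columns give each peak's position, an integer score, a fold enrichment (a ratio over background at the summit), and the -log10 of a p-value and of a q-value. The smallest deposited -log10 q lay between 2.00 and 2.02 in the 4 lists, the place of a q threshold of 0.01. The lists hold no read counts, so sequencing depth is not stated in them. A peak list shows where the signal passed a threshold, so a region without a peak may still carry the mark below that threshold, and the number of peaks moves with depth and with enrichment.

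Relative depth was recovered from the authors' fold and -log10 p. In the caller's formula these values fix the number of reads at a summit up to a scaling factor, which was searched for in each library. Whole numbers of reads were found for 100% of the peaks in each library, within 0.001 on the -log10 p, and 49.7 to 50.1% of these numbers were odd, which excludes a smaller factor that would make every number even. On simulated peaks with 6 known factors, 100% of the reads were recovered. Relative to control replicate 2, the ChIP depth came out as 0.940 for control replicate 3, 0.786 for lactate replicate 2 and 0.887 for lactate replicate 3. The input depth behind the peaks was 1 and 1.00 in the control and 0.958 and 0.959 in the lactate libraries, so the libraries of a treatment appear to share an input.

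Peaks were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and tests were run with scipy 1.17.1. Plots were drawn with matplotlib 3.10.9. Peaks of the 4 libraries were merged into regions where they shared at least 1 bp, and a region was scored as present in each library with a peak in it. Control-only regions hold a peak in both control libraries and in neither lactate library, and lactate-only regions the converse. The mixed pairs of libraries give the count beside these. The number of peaks, the covered length, the share of peaks at gene ends and the number of genes with such a peak were compared by an exact two-sided permutation test over the 6 assignments of the labels, whose smallest p is 0.333. The Jaccard index is the number of bases shared by 2 lists over the bases in either.

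Genes came from a RefSeq table of GRCh38.p14, with 20033 protein-coding genes. That table gives gene spans without strand, transcripts or exons. The design called for windows of 1 kb on either side of the 5' end, and windows of 1 kb on either side of both gene ends were used in its place, so a gene-end peak can lie at either end of the gene. Exonic and intronic positions were not assigned. Expected shares of peaks at gene ends came from 100 circular shifts of the peaks along their chromosomes. The gene groups were 20 lists, 19 written by hand and 1 for the olfactory receptor family, and all 533 written members matched a gene. Each list was compared with the other coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 20 lists, in 3 families of tests. Intervals on list shares are exact Clopper-Pearson 95% intervals.

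Named genes follow a rule. From the glycolysis, transport and lactylation lists, up to 6 members with the best mean rank of fold enrichment and up to 6 control-only or lactate-only members were named, and from each other list up to 3 by the same rule. The 10 best-ranked genes present in all 4 libraries, control-only and lactate-only were named, with the genes that share their window, and the 5 best-ranked regions of each kind. For list members, shared windows are named only for some glycolysis and transport genes. Other members are named where a count was small or a locus was singled out after its values were seen, which holds for the mixed members of the main lists and the broad domains. Some genes and regions that the rule takes are not reported here.

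Groups, tests, lists, naming rule and the first set of other settings were fixed before the data were examined. That set held a -log10 q of at least 5, an equal number of 37951 peaks per library, all contigs, a reciprocal overlap of 50%, windows of 3 kb, each library left out in turn, and a replicate block. Peaks over gene bodies, peaks joined within 1 kb, and all settings for the number of peaks of at least 2 kb were chosen after seeing the data. The merging and list tests were tested on simulated data. All 900 control-only, 300 lactate-only and 3000 shared regions planted among 6000 were found. A planted list of the size of the glycolysis list passed in 193 of 200 draws over the 20033 genes. Of 3800 tests of other lists, 11 passed. The planted share was higher than the 23.7% found for the glycolysis list, so these draws do not give the power at that share.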

Results

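Lactylation of histone H4 at lysine 5 (H4K5la), a lactate-derived acyl mark on chromatin, was mapped by chromatin immunoprecipitation and sequencing in PLC/PRF/5 cells, an established human hepatocellular carcinoma line. Cells were either left untreated or cultured with 20 mM lactate for 24 h. Peak lists were analysed for 2 control libraries (replicates 2 and 3) and 2 lactate libraries (replicates 2 and 3). The 2 input libraries carry no antibody and have no peak list, and were not analysed here. The lists held 52215 and 52959 peaks for control replicates 2 and 3, and 37951 and 38402 peaks for lactate replicates 2 and 3. All coordinates are on hg38, and every peak lay on chromosomes 1 to 22 or X. The fold enrichment of a peak over its background is the authors' value throughout, and is used here to describe and rank peaks within a library. Nothing in the labels says whether the replicates came from separate cultures. The permutation and sign-flip p-values below therefore refer only to the spread between these libraries, which may be technical. Fisher's exact tests take genes as the units and do not measure that spread.

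The first comparison asked how much of the genome carried H4K5la peaks with and without added lactate. Control libraries held 52587 ± 526 peaks (SD, n = 2) covering 41.0 ± 0.00649 Mb, and lactate libraries held 38176.5 ± 319 peaks (SD, n = 2) covering 21.9 ± 0.198 Mb. The ratio of lactate to control was 0.726 for the number of peaks and 0.534 for the covered length. Broad domains over genes such as BIN1 (a membrane-bending adaptor), ARFGAP1 (a Golgi GTPase-activating protein), MAD1L1 (a spindle checkpoint protein) and BRSK2 (a protein kinase) were each 1 peak in either control library and 4 to 7 separate peaks in the lactate libraries. These domains were chosen after their values were seen, as the broadest control regions among those with 1 peak in each control library. Both lactate libraries lay outside the range of the control libraries for each of these measures.

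The difference was 27.4 times the larger group SD for the number of peaks and 96.5 times for the covered length. The libraries of a treatment appear to share an input, so these SDs hold no spread between inputs. Input and treatment therefore cannot be told apart in these multiples. With 2 libraries against 2, the exact two-sided permutation test cannot give a p below 0.333, and both measures gave p = 0.333. The median peak width was 542 ± 7.07 bp in control and 442.5 ± 7.78 bp in lactate libraries (SD, n = 2). Peaks of at least 2 kb numbered 2627 and 2619 in the control libraries and 317 and 292 in the lactate libraries, a ratio of 0.116 (exact permutation p = 0.333). In settings chosen after seeing the data, the ratio was 0.344 for peaks of at least 1 kb, 0.035 for peaks of at least 3 kb, and 0.372 for peaks of at least 2 kb after joining peaks within 1 kb. Peaks of at least 5 kb numbered 225 and 215 in the control libraries and 0 and 1 in the lactate libraries. The median fold enrichment was close in the 2 groups, at 7.37 ± 0.337 in control and 7.24 ± 0.119 in lactate libraries (SD, n = 2; exact permutation p = 1).

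**Figure D1:**
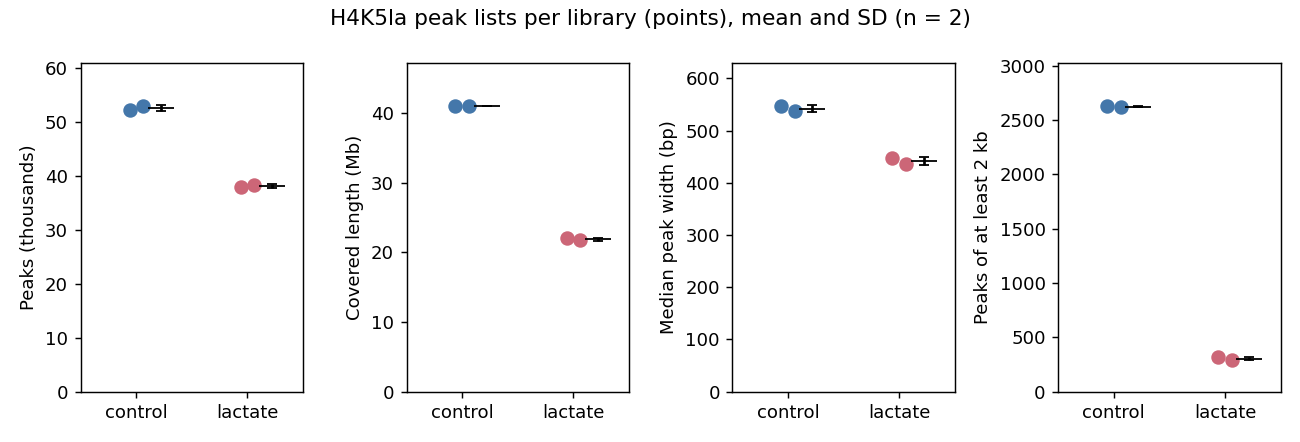
Number of peaks (axis in units of 1000), covered length in Mb, median peak width in bp and number of peaks of at least 2 kb, for each H4K5la library as a point (control in blue, lactate in red), with the group mean and SD beside it (n = 2). The lactate libraries lie below the control libraries in all 4 panels, with 317 and 292 peaks of at least 2 kb against 2627 and 2619.

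The domain over BIN1 (chromosome 2, 127047809 to 127059300) was 11370 and 11457 bp wide in the control libraries, while the widest lactate peaks within it were 2033 and 1915 bp. At MAD1L1 (chromosome 7, 1944511 to 1955508) the control peaks were 10998 and 10939 bp wide and the widest lactate peaks 3054 and 2963 bp. At ARFGAP1 (chromosome 20, 63280531 to 63291559) the control widths were 11029 and 10954 bp against 1546 and 1445 bp with lactate. TSC2, which encodes tuberin, an inhibitor of mTORC1 signalling, held control peaks of 11327 and 8949 bp and lactate peaks of at most 387 and 627 bp. Of 1902 regions whose peak was at least 2 kb wide in both control libraries, 92.6% still held a peak in both lactate libraries. Over all 1902 regions the mean number of peaks per control library was 1.19, and the median of the narrower control width was 2701 bp. Over those held in both lactate libraries, the mean number of peaks per lactate library was 1.97. The median there of the widest lactate peak, averaged over the 2 libraries, was 1107 bp. The regions were chosen on their control width, so part of this gap may come from that choice. Regions with control peaks under 500 bp held a peak in both lactate libraries in 35.9% of 16996 cases.

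PFKL, the liver form of the glycolytic enzyme phosphofructokinase, lies on chromosome 21 from 44300053 to 44327373. Within the gene, control replicate 2 had a peak of 8761 bp and control replicate 3 a peak of 8882 bp. The same span held 3 peaks in lactate replicate 2 and 4 in lactate replicate 3, and the widest lactate peaks in and around the gene were 1375 and 1118 bp.

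**Figure D2:**
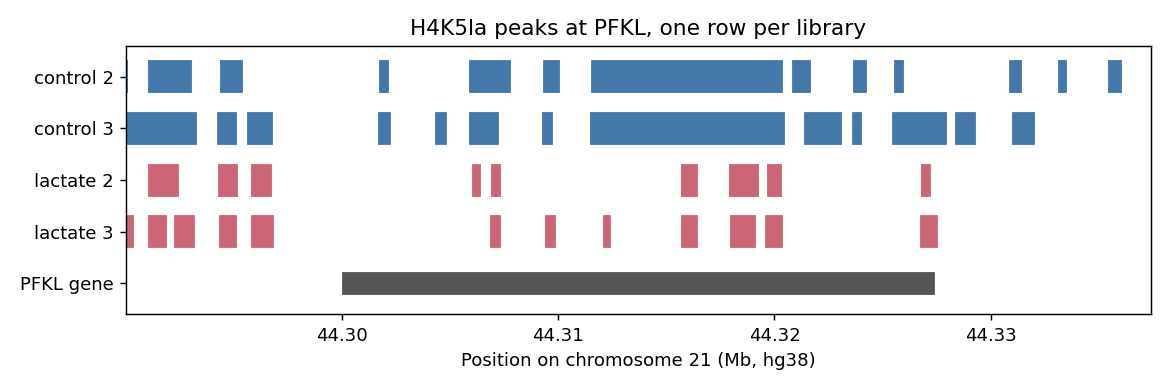
Peaks of the 4 H4K5la libraries along chromosome 21 (position in Mb, hg38) around PFKL, with control peaks in blue, lactate peaks in red and the annotated gene span in grey. Each control row holds 1 peak of 8761 or 8882 bp inside the gene, where the lactate rows hold 3 and 4 shorter ones; the locus was chosen after its peaks were seen.

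The second comparison asked which regions were shared and which were found with 1 treatment alone. Merging the 4 lists gave 71122 regions, of which 20499 (28.8%) held a peak in all 4 libraries. Regions ranking among the highest by fold enrichment in all 4 lay inside SRGAP3, in a stretch of chromosome 21 from 41668103 to 41669794, and near FNDC3B. The SRGAP3 region (chromosome 3, 9110195 to 9111016) had a fold enrichment of 15.8 and 22.3 in control and 28.2 and 30.6 in lactate libraries. A further top region on chromosome 8, from 57209632 to 57210502, lay 215765 bp from the nearest coding gene, BPNT2. Regions with peaks in both control libraries and neither lactate library numbered 10354, and regions with peaks in both lactate libraries and neither control library numbered 1953.

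Control-only regions with the highest ranks lay in ASTL, in TSPEAR with KRTAP10-8, in the long noncoding RNA gene MALAT1, in LOC105371024 with LOC440313, and in ASIC4. The MALAT1 region (chromosome 11, 65497514 to 65498614) had a fold enrichment of 14.3 and 19.3 in the control libraries. Lactate-only regions with the highest ranks lay in LOC101928012, LOC105373430, ARAP3 and NAV2, and 11328 bp from IWS1. The NAV2 region (chromosome 11, 19879765 to 19880259) had a fold enrichment of 16.3 and 15.2 in the lactate libraries. The 4 mixed pairs of 1 control and 1 lactate library shared between 1100 and 1236 regions of their own, below both counts. Of the 38825 regions in both control libraries, 26.7% held no lactate peak, and of the 25717 regions in both lactate libraries, 92.4% held a control peak.

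The Jaccard index of covered bases was 0.607 between the control libraries and 0.513 between the lactate libraries, and lay between 0.367 and 0.384 for the pairs across treatments. The within-treatment mean exceeded the between-treatment mean by 0.185, while the other splits of the 4 libraries gave -0.0916 and -0.0932. These differences cancel over the splits by construction, so the negative values add no separate support. The smaller covered length with lactate also limits the index across treatments. By number, 77.8 to 80.3% of lactate peaks overlapped a peak of a control library, against 72.9% and 72.3% for the other lactate library. When each library was restricted to its 37951 peaks of highest -log10 p, control-only regions numbered 4929 and lactate-only regions 3790. Under a reciprocal overlap of 50%, lactate-only regions numbered 6058, control-only regions 13938 and regions in all libraries 12519. Leaving out control replicate 2, control replicate 3, lactate replicate 2 or lactate replicate 3 gave 3392, 3925, 4915 and 5140 lactate-only regions and 19204, 19294, 14171 and 14568 control-only regions, since 1 library then stands for its group.

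The third comparison asked which genes carried the mark at their ends. A gene was counted when a peak overlapped the 1 kb on either side of its annotated start or end, because the gene table used gives no strand and the 5' end could not be singled out. The peaks of a gene counted in all 4 libraries need not overlap each other or lie at the same end. MYLK2 (a myosin light chain kinase), GRIK1 (a kainate receptor subunit), SLFN11 (a DNA damage response factor), CHSY1 (a chondroitin synthase) and TP53TG5 with SYS1 led the 2074 genes with such a peak in all 4 libraries. They were followed by ZMAT4, the chromatin remodeller CHD2, LOC124905027, the purine synthesis enzyme IMPDH1 and the phosphatase INPP5D. Control libraries had a gene-end peak at 5034.5 ± 254 of 20033 protein-coding genes and lactate libraries at 3297.5 ± 72.8 (SD, n = 2), a ratio of 0.655 (exact permutation p = 0.333). With 37951 peaks in each library the ratio was 0.945.

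GRIK1 had a fold enrichment of 13.9 and 18.5 in control and 24.1 and 32.8 in lactate libraries, in peaks spanning 29938909 to 29939876 of chromosome 21 in control replicate 2. The MYLK2 values were 14.9 and 19.2 in control and 24.0 and 30.2 in lactate libraries. Gene-end windows were overlapped by 10.3 ± 0.490% of control peaks and 8.85 ± 0.143% of lactate peaks (SD, n = 2), a difference of -1.43 percentage points (exact permutation p = 0.333). The difference was -0.577 points with equal numbers of peaks and -0.204 over gene bodies (exact permutation p = 0.667). Shifting the peaks along their chromosomes gave 3.92% and 3.89% for the control and 3.54% and 3.62% for the lactate libraries. Peak summits lay mostly inside coding genes away from their ends, in 59.0% and 59.0% of control and 59.7% and 59.8% of lactate peaks, where shifted peaks gave 41.8%, 41.9%, 41.2% and 41.5%.

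Control-only genes numbered 1198. By rank they were led by SLC23A1 (a vitamin C transporter) with MZB1, LGALS2 (a galectin) with CDC42EP1, FAM174B, DBNDD1 with DRC4, and PEMT, the liver enzyme that makes phosphatidylcholine by methylation. ASB7 with LINS1, the chemerin receptor gene CMKLR1, PPP6R1 with TMEM86B, and TRIM11 with TRIM17 completed the top of that list. The peak at PEMT spanned 17506362 to 17513204 of chromosome 17 in control replicate 2 and 17505627 to 17513081 in control replicate 3, with a fold enrichment of 13.9 and 12.1. SLC23A1, FAM174B, DBNDD1, PEMT, ASB7 and PPP6R1 held a peak elsewhere in the gene in both lactate libraries. LGALS2, LINS1, CMKLR1 and TRIM11 held none there. With windows of 3 kb SLC23A1, DBNDD1, PEMT and PPP6R1 had a peak in all 4 libraries, and LGALS2 had one in 1 lactate library, so these were no longer control-only.

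Lactate-only genes numbered 153. They were led by MYH10 and NDEL1, which share a window (a nonmuscle myosin heavy chain and a dynein regulator), TSHZ3, TDRD15, and GPATCH11 and HEATR5B, whose shared window also touches that of EIF2AK2. CCT7 (a chaperonin subunit) with FBXO41 and PRADC1, LRRC71, the neuroglobin gene NGB and the ubiquitin ligase gene UBE3C followed. The peak between NDEL1 and MYH10 spanned 8474810 to 8475177 of chromosome 17 in lactate replicate 2, with a fold enrichment of 13.9 and 14.3 in the 2 libraries. MYH10, NDEL1, TSHZ3, LRRC71 and UBE3C held a peak elsewhere in the gene in both control libraries, and TDRD15, GPATCH11, HEATR5B, CCT7 and NGB held none. With windows of 3 kb MYH10, NDEL1 and CCT7 had a peak in all 4 libraries, and LRRC71 had one in 1 control library. Mixed pairs of libraries shared between 72 and 108 genes of their own. With 37951 peaks in each library, control-only genes numbered 530 and lactate-only genes 387. Without control replicate 2, control replicate 3, lactate replicate 2 or lactate replicate 3, lactate-only genes numbered 259, 327, 362 and 373, and control-only genes numbered 1961 without control replicate 2.

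The last comparison asked whether genes of glycolysis, lactate handling and other fixed groups stood apart. The series title names glycolysis as its subject. Of 38 glycolysis genes, 9 (23.7%) had a gene-end peak in all 4 libraries, against 10.3% of the other genes (Fisher's exact test, p = 0.0136, Benjamini-Hochberg adjusted p = 0.0909 over 20 lists). Among them were ALDOA, GAPDH, HK1, HK3, PFKFB4 and PGAM2. Of these, ALDOA shares a window with LOC112694756, GAPDH with IFFO1, HK3 with UNC5A, and PFKFB4 with COL7A1 and UCN2. The best-ranked peaks of ALDOA and of PFKFB4 lay at different ends of the gene in different libraries. LDHA and LDHB, which encode the subunits of lactate dehydrogenase, and PFKM, the muscle phosphofructokinase gene, had a peak in both control libraries and neither lactate library. LDHAL6B, a lactate dehydrogenase-like gene, had one in both lactate libraries alone, and PFKL and PFKP were mixed. PFKM shares a window with ASB8 and SENP1, PFKL with AIRE and CFAP410, and PFKP with LOC124902536 and PITRM1. With equal numbers of peaks LDHA, LDHB and PFKM each kept a peak in 1 control library alone, so none was control-only, and PFKL had one in both lactate libraries alone. The other 23 glycolysis genes had no gene-end peak in any library.

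HK1 and PGAM2 had the best ranks among these 9 genes. The HK1 peak at the upper end of the gene on chromosome 10 had a fold enrichment of 8.20 and 12.4 in control and 12.5 and 11.7 in lactate libraries. At HK3 the control values were 16.6 and 18.0 and the lactate values 2.81 and 3.06, which describe each list and do not measure a change. The LDHA peak spanned 18394710 to 18395086 of chromosome 11 in control replicate 2 and 18394623 to 18394973 in control replicate 3. With an equal number of peaks per library the glycolysis list exceeded the other genes by 5.05 percentage points (Fisher's exact test, adjusted p = 0.773), against 13.4 points in the full lists.

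Of 21 genes for glucose and lactate transport and sensing, SLC2A1, SLC2A4 and the lactate exporter gene SLC16A3 had a gene-end peak in all 4 libraries. HCAR1, the lactate receptor gene, had one in the control libraries alone, BSG and SLC2A6 were mixed, and 15 had none. SLC2A4 shares a window with YBX2, SLC16A3 with CSNK1D, and SLC2A6 with CACFD1. With equal numbers of peaks SLC2A1 had a peak in both lactate libraries alone, SLC16A3 was no longer in all 4, and HCAR1 had one in 1 control library alone. Of 23 genes for enzymes that write or remove lactyl and related acyl marks, KAT2A, KAT8 and SIRT2 had a peak in all 4 libraries, AARS2, KAT2B and KAT7 were mixed, and 17 had none. The adjusted p for peaks in all 4 libraries was 0.861 and 1 for these lists (Fisher's exact test).

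**Figure D3:**
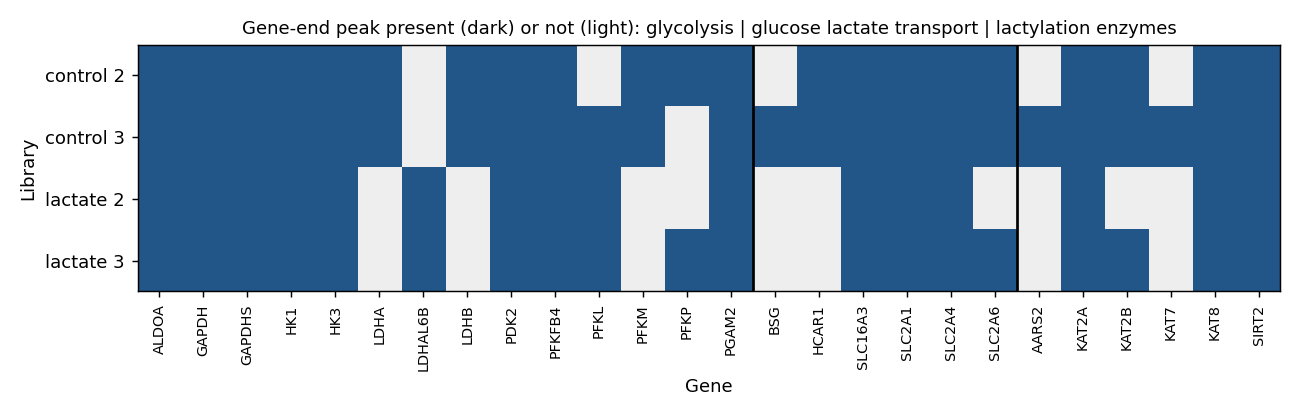
Presence (dark) or absence (light) of a gene-end peak in each of the 4 H4K5la libraries (rows) for genes (columns) of the glycolysis, transport and lactylation lists with a peak in at least 1 library, leaving out any not reported here. LDHA, LDHB, PFKM and HCAR1 are dark in the control rows alone, and LDHAL6B in the lactate rows alone.

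Olfactory receptor genes, which are silent in most tissues, were the list that passed the test for peaks in all 4 libraries. They had such a peak at 4 of 390 genes (1.03%, exact 95% interval 0.280 to 2.61%) against 10.5% of the other genes (Fisher's exact test, adjusted p = 1.22e-12). The 4 were OR6B3, OR2V2, OR1K1 and OR10S1, and OR1F1 was control-only. Markers of stromal and endothelial cells had one at 6 of 19 genes (31.6%, exact test, adjusted p = 0.0909), with CDH5, PDGFRB and COL1A2 ranking highest, and LRAT and ACTA2 lactate-only. This list passed the exact test with the stricter threshold (adjusted p = 0.0415) and with equal numbers of peaks (adjusted p = 0.0305), and not with windows of 3 kb (0.337), over gene bodies (0.260) or with any 1 library left out (0.0986 to 0.251). Oncofetal and liver cancer genes had one at 5 of 17 (29.4%, exact test, adjusted p = 0.127), namely TERT, IGF2, ANPEP, SALL4 and DLK1, with CD44 control-only. Immune cell markers had one at 5 of 23 (exact test, adjusted p = 0.329), led by CD79B, GNLY and NKG7 with CD4, CD68 and ITGAX control-only, and genes of epithelial to mesenchymal transition at 4 of 20 (adjusted p = 0.486), led by SPARC, TWIST2 and MMP14, with TWIST1 lactate-only.

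The remaining lists did not pass the Fisher's exact test, with adjusted p from 0.678 to 1, and their sizes of 9 to 78 genes leave wide intervals. Oxidative phosphorylation genes had a peak in all 4 libraries at 10 of 72, led by NDUFS6, ATP5F1E and UQCRQ, with COX6C and NDUFA11 control-only and NDUFA2 lactate-only. Ribosomal protein genes had one at 8 of 78, led by RPL31, RPL12 and RPL38, and 9 were control-only, among them RPL27A, RPL7A and RPS14. Tricarboxylic acid cycle genes had one at 2 of 25 (IDH2 and OGDH) with SUCLG1 and IDH3B control-only, and pentose phosphate genes at 2 of 9, among them TKT. Gluconeogenesis genes had one at 1 of 9 (PC) with SLC37A4 control-only, and hypoxia response genes at 3 of 28 (CA12, ADM and DDIT4) with P4HA1, STC2 and BHLHE40 control-only. Hepatocyte genes had one at 3 of 37, among them APOC3 and HNF4A, with APOA1 control-only and CYP1A2 lactate-only. Cell cycle genes had one at 3 of 35 (BUB1, PLK1 and MYC), with CCNB2 and CDC20 lactate-only and RRM1 control-only, and sterol and fatty acid synthesis genes at 4 of 26, led by FADS2, MVK and SCAP, with FDPS control-only. Amino acid stress genes had one at 2 of 20 (SLC7A5 and ATF5), with SHMT2, PSAT1 and CHAC1 control-only. Neuronal genes had one at 2 of 18 (CAMK2A and SYT1), with NEFL, SNAP25 and RBFOX3 among 4 control-only members. None of the 15 histone H4 genes had one, with H4C13 control-only and H4C6 lactate-only.

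No list passed the test for its share of control-only genes among those with a peak in both control libraries. With at most 4 such genes each, 4 of the 20 lists could not have passed alone at any share. The smallest unadjusted p was 0.0656 for neuronal genes (4 of 6, Fisher's exact test), and the smallest adjusted p was 0.757. No list passed for its share of lactate-only genes either, with 3 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.170, for the stromal and endothelial markers LRAT and ACTA2 (2 of 13). Olfactory receptors did pass this test, as a lower share, with equal numbers of peaks (0 of 382 genes against 2.52%, Fisher's exact test, adjusted p = 0.00284) and with each library left out in turn (0 of 380 or 381). These tests treat genes as the units, so they compare lists within these libraries and say nothing of the spread between replicates.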

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

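The gene-body, joined-peak and broad-peak settings were chosen after seeing the data. The numbers of peaks, covered length, share of peaks at gene ends, number of genes with a gene-end peak, overlap between libraries and number of peaks of at least 2 kb kept their direction in each setting run, and the exact permutation test used cannot pass its threshold with 2 libraries per group. Using all contigs moved nothing, since the lists hold no others. With an equal number of peaks, lactate-only and control-only regions numbered 3790 and 4929 and the corresponding genes 387 and 530, while 2 lists passed for peaks in all 4 libraries (olfactory receptors, lower, and stromal and endothelial markers, higher) and 1 for lactate-only genes (olfactory receptors, lower). The ratio of genes with a gene-end peak was then 0.945 and the difference in share -0.577 points. The stricter threshold gave the same 2 lists for peaks in all 4 libraries. A reciprocal overlap of 50% gave 6058 lactate-only regions and 12519 regions in all libraries. Gene bodies gave 2 lists for peaks in all 4 libraries (olfactory receptors and ribosomal proteins, both lower) and 1 for control-only genes (ribosomal proteins, higher), with a difference in share of -0.204 points. With each library left out in turn, lactate-only regions ranged from 3392 to 5140, control-only regions from 14171 to 19294, lactate-only genes from 259 to 373, control-only genes from 1552 to 1961, and 1 list, olfactory receptors with a lower share, passed for lactate-only genes each time. Counts rise there because 1 library then stands for its group; for the other shifts the cause was not tested. Of 57 genes examined singly, the difference between lactate and control libraries with a gene-end peak moved without reversing for 13 with equal numbers of peaks, 11 with windows of 3 kb, 8 with the stricter threshold and 15 over gene bodies. KAT2B, mixed in the full lists, had 1 more lactate than control library with a gene-end peak under the stricter threshold and with equal numbers of peaks, the reverse of the full lists.

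The replicate numbers give no sign of pairing, since presence differences between replicates 2 and 3 correlated by 0.00478 across 71122 regions in the 2 groups. With the numbers as a block, the paired ratio was 0.726 for the number of peaks, 0.534 for the covered length and 0.655 for the genes, and the difference in share was -1.43 percentage points, each with an exact sign-flip p of 0.5, the smallest 2 pairs allow. Windows at the 5' ends of all transcripts and random lists matched on GC content were not run, as no strand and no genome were used here.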

Other observations

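H4K5la peaks were unevenly spread over the chromosomes. Chromosome 19 held 49.2 control and 33.8 lactate peaks per Mb of annotated extent, followed by chromosomes 22, 17 and 20 with 47.8, 39.7 and 39.4 control peaks per Mb. Chromosome X held 2.33, chromosome 4 held 6.93 and chromosome 13 held 7.98 control peaks per Mb. The ratio of lactate to control peaks lay between 0.684 on chromosome 3 and 0.821 on chromosome 21. Over gene bodies with 1 kb on either side, a setting chosen after seeing the data, ribosomal protein genes had a peak in all 4 libraries at 12.8% of 78 members against 28.6% of other genes (Fisher's exact test, adjusted p = 0.0150). In the same setting 11 of 24 ribosomal protein genes with a peak in both control libraries had none with lactate, against 14.3% of other genes (Fisher's exact test, adjusted p = 0.00422); ribosomal protein genes are short, and length was not matched.

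The tests of sequencing depth, enrichment and input below were chosen after the result was seen, and the tests of joining, chromosome ends and neighbourhoods were set before theirs, the last on 3 lists picked after their shares were seen. The first pattern is the smaller number of peaks with lactate. After scaling control summit reads to a lactate library's depth, at least 99.5% of control peaks passed its lowest -log10 p in all 4 pairs. A share of 71.7 to 73.5% would match the lactate lists. That scaling cannot test sequencing depth, as the ChIP depth cancels in it and leaves the input ratio. Control replicate 3 kept 99.8% at both 0.836 and 0.943 of its depth. The peak counts do argue against lower depth as the whole cause. Control replicate 3, at 0.940 of the depth of control replicate 2, held 52959 peaks against 52215. Lactate replicate 3, at 0.943 of the depth of control replicate 3, held 38402. A uniformly weaker enrichment is not decided, as summit reads have no background taken off. The authors' fold was lower with lactate at broad regions such as ARFGAP1, with 10.4 and 12.6 in control and 5.32 and 4.81 in lactate libraries. Near PIM3 it was not lower, with 3.76 and 6.49 against 5.62 and 6.44. By group mean, PIM3 was the only exception among the broadest control regions examined. At MAD1L1 the fold was 7.81 and 9.42 in control and 4.12 and 5.09 in lactate libraries. At KCNT1 it was 7.13 and 11.7 against 3.21 and 4.12. The lactate to control ratio of summit reads per sequenced read was 1.24 at 676 regions of at least 3 kb in the controls, with 1.10 between the control replicates. These are 96.3% of the 702 such control regions, so requiring a lactate peak removed few; over all regions in both controls it kept 52.8%, so the ratio there decides nothing and is not used. The input stays open: the lactate libraries share an input at 0.959 of the control input's depth, so input and treatment cannot be told apart. The lactate treatment itself stays among the open explanations, as untested.

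The second pattern is the replacement of broad control peaks, as at BIN1, ARFGAP1 and PFKL, by several narrower ones with lactate. A different joining of neighbouring peaks is argued against as the whole cause, since after joining peaks within 1 kb the ratio of peaks of at least 2 kb was 0.372, up from 0.116 and still below the bound of 0.5 set in advance; part of the narrowing may come from splitting. The change was not restricted to chromosome ends, with a ratio of 0.109 outside the outer 5 Mb and 0.120 within it. Most broad control peaks did lie in the outer 5 Mb, 1660 of 2627 in control replicate 2 and 1739 of 2619 in control replicate 3. Depth as the whole cause is argued against: control replicate 3, at 0.940 of the depth of control replicate 2, had 0.997 times as many such peaks, while lactate replicate 3, at 0.943 of the depth of control replicate 3, had 0.111 times as many. The lactate treatment and the different input stay open, both untested. The local background behind the fold was not compared between treatments at these domains.

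The third pattern is the low share of olfactory receptor genes with a gene-end peak in all 4 libraries. At the share of the other genes 41.1 of the 390 would be marked, and in 10000 random lists matched on the regions between 5 and 250 kb away the mean was 22.3, so a peak-poor neighbourhood may account for part of the deficit. It is argued against as the whole cause, since 0% of the matched lists had as few as the 4 observed. The random genes were drawn singly, so neither clustering within the family nor gene length was matched, and the share rests on that. GC content was not tested, and no biological explanation was tested. The glycolysis and stromal and endothelial lists missed the adjusted threshold. Stromal and endothelial genes had a median of 1 region nearby against 3 for other genes, which argues against a peak-rich neighbourhood behind their 6 marked genes (0.43% of matched lists had as many). Glycolysis genes had a median of 4. Matched lists had a mean of 4.40 marked genes, against 3.92 at the share of the other genes, and 2.22% had as many as their 9. The list was picked after its share was seen, so that 2.22% does not test the excess and draws no conclusion on its source.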
